A study of Mus musculus with 3 samples.

How the data were processed

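Long-term haematopoietic stem cells, sorted from mouse bone marrow as lineage-negative, Kit-positive, Sca-positive, Flk2-negative, CD48-negative and CD150-positive cells, were kept overnight in serum-free medium and exposed to 0, 0.02 or 2.5 Gy of gamma radiation, per the labels' protocols. RNA was taken 2 hours later and hybridised as biotin-labelled target made with the Affymetrix whole-transcript sense kit, per the labels' protocols. The 3 arrays hold 1 array per dose. The groups are called unirradiated, low dose (0.02 Gy) and high dose (2.5 Gy).

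The values analysed are the authors' deposited log2 values, 1 per probe set and array, for 25206 probe sets named by Entrez gene identifier. Partek is named without a version or a role, per the submitters' processing notes; the background correction, the normalization, the summarisation and any centring are not given in the sources used here. The log2 scale was read from the deposited values, which run from 1.55 to 12.4. The deposited values gave array medians of 4.60 (unirradiated), 4.54 (low dose) and 4.55 (high dose), so the arrays were not on identical distributions. No scanner files were used here, so signal over background and detection could not be assessed per probe set.

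Gene names came from the platform annotation table. Of the probe sets, 23185 had 1 gene symbol, 0 had several and 2021 had none in that table; the unnamed probe sets stayed out of every gene comparison. No gene symbol had more than 1 probe set. Genes with a mean over the 3 arrays of at least 4.553, the median of the named genes, were kept, which left 11593. Of these, 1552 belong to predicted genes or to families with near-identical copies (olfactory and vomeronasal receptors, immunoglobulin and T cell receptor segments, microRNAs, histones and the like); they were counted and, histones of a fixed list apart, not named. The families were set by symbol and gene type, so other multigene families were not removed. Bax, Ly6a and Trp53 are not analysed here.

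Differences between arrays were taken gene by gene on the log2 scale, in 3 comparisons: low dose minus unirradiated, high dose minus unirradiated and high dose minus low dose. With 1 array per group there is no replicate spread, so no test was run and no p-value is given; genes were counted by a fixed size of 2-fold. The number of arrays limits the precision of every value. For 32 gene lists fixed before the data were examined (901 of 1005 symbols matched, 30 of them through an older name), the median difference of the members past the level minimum was set among the medians of 10000 random lists of the same size drawn from genes of like level in 20 bins. A list of at least 5 members whose median lay outside the central 95% of random lists is called outside the random range; this describes these arrays and is not a test of dose. Median centring adds one constant per comparison, which cannot move a percentile or a correlation, so it is not counted among the 6 alternatives of a list call. For genes drawn independently, 1.55 of 31 lists would lie outside in each comparison. Genes of a list can move together and some genes are on several lists, so more may lie outside without any effect of dose.

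Genes named in the text were fixed by rule before the data were examined: for each comparison the 10 highest and 10 lowest differences outside the families, the 4 members of each list with the largest difference, and 12 p53, sorting and stem cell genes whatever their values (those of them measured are given). Genes named outside this rule are marked as such. Because both dose comparisons share the unirradiated array, their correlation was set beside 100 simulations of 3 arrays without any effect. The simulated noise was normal, with an SD per level bin taken from high dose minus low dose, which is not replicate noise.

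The counting and list steps were tested on simulated data for high dose minus unirradiated, with 11593 genes and 200 changed genes. The simulated noise was normal and scaled from the robust SD of high dose minus low dose by level bin, which discounts extreme values. At a seeded log2 change of 1.50, 96.0% of the seeded genes passed 2-fold, at 3.00 all did, and 0.281% of unchanged genes passed. That last share follows from the noise chosen and is not a false-call rate for these arrays, where 1.73% to 2.50% of genes passed. Of 20 lists of 22 genes shifted by 0.5, 100% lay above the 97.5th percentile, and 5.5% of 200 unshifted lists lay outside the random range. That shift is large beside the SD of random-list medians (0.078 for the 22 NF-κB genes at the high dose). Apart from NF-κB, no list called below had a median above 0.39, so the check says little about shifts of that size.

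The alternatives were no level minimum, a minimum at the 75th percentile, quantile normalization, median centring, loess of each array over mean level (span 0.3), fold sizes of 1.5 and 3, families left out, list means and Spearman's rho. Of 2 alternatives chosen after seeing the data, one drew the random lists from protein-coding genes outside the families and the other held both arrays of a comparison to the level minimum in the counts. For most named genes below the minimum on 1 array of a comparison, both values are given and no difference. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.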

Results

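Gene expression was measured on 3 arrays of sorted mouse long-term haematopoietic stem cells, with 1 array for unirradiated cells, 1 for cells given 0.02 Gy and 1 for cells given 2.5 Gy, all taken 2 hours after exposure. The series asks how these cells respond within hours to low doses of gamma radiation, with the unirradiated cells as reference. There were no replicates, so no difference below has a replicate check and each is a difference between single arrays. Across all probe sets the arrays correlated at r = 0.957 (unirradiated with low dose), 0.965 (unirradiated with high dose) and 0.960 (low with high dose), across genes, which are not independent replicates. Both irradiated arrays differed from the unirradiated array by level: the median difference was −0.08 (low dose) and −0.07 (high dose) in the fifth decile of level and 0.19 and 0.14 in the top decile, while high dose minus low dose was −0.04 there.

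**Figure D1:**
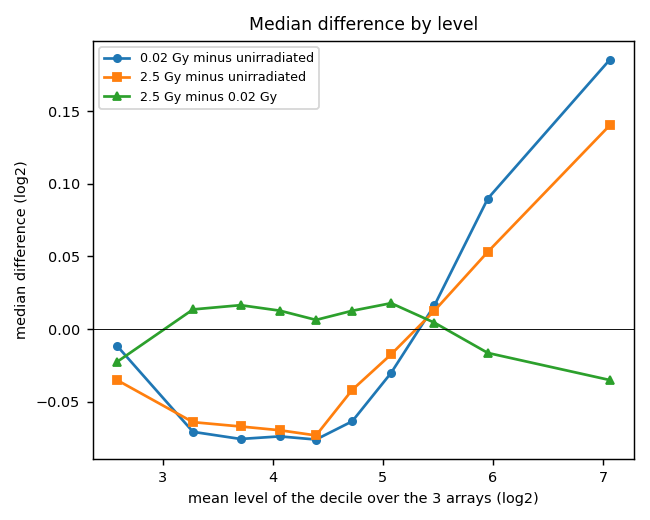
Median log2 difference (vertical axis) in each of 10 deciles of mean log2 level over the 3 arrays (horizontal axis), with 1 line per comparison. Both comparisons with the unirradiated array run from about −0.07 at middle levels to 0.19 (0.02 Gy) and 0.14 (2.5 Gy) in the top decile, and the comparison between the doses stays within 0.04 of 0.

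Genes of the sorting markers and of stem cell identity were read on each array. Kit, the stem cell factor receptor used in the sort, was at 8.58, 8.78 and 8.50 (log2, unirradiated, low and high dose), and Slamf1, which encodes CD150, at 5.24, 4.75 and 4.84. Cd48, a gene of the marker selected against, lay below the level minimum on every array (3.62, 3.31 and 3.40). Flt3, which encodes Flk2, was at 4.60, 4.95 and 4.93. Counts of list members here are of those past the level minimum. For the 32 stem cell identity genes, the median difference from unirradiated was 0.22 at the low dose and 0.16 at the high dose, at percentiles 95.5 and 91.5 of random lists. Bmi1, a Polycomb gene needed for stem cell self-renewal, was 0.78 higher at the low dose and 0.37 higher at the high dose.

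At 2.5 Gy, the array held higher values for genes of NF-κB signalling and inflammation than the unirradiated array. The median of the 22 members past the level minimum, of 32 measured, was 0.94, a 1.92-fold difference, above all 10000 random lists, whose highest median was 0.47. Of these members, 20 were above 0, and 10 were at least 2-fold higher. They included Nfkbie (2.01, from 4.62 to 6.63), an inhibitor of NF-κB, the chemokine genes Cxcl2 (1.76) and Cxcl10 (from 4.42, below the level minimum of 4.553, to 5.88), and Birc3 (1.54), an inhibitor of apoptosis. Without the level minimum the median of the list was 0.37, still above every random list. Tlr4, a receptor for lipopolysaccharide, was lower by contrast, at −0.71; it was chosen after its value was seen. On the same array, among markers of mature myeloid cells, S100a8 (1.24), S100a9 (1.56) and Ly6c2 (1.04) were at least 2-fold higher, while the median of the 16 members was −0.02 (percentile 34.8).

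p53 target genes were also higher at 2.5 Gy. The median of the 25 members past the level minimum, of 38 measured, was 0.29 (percentile 99.9 of random lists), and their mean was 0.47. Of these, 21 were above 0 and 4 were at least 2-fold higher. These were Ccng1 (2.02, from 7.32 to 9.34; Entrez gene 12450), Cdkn1a (1.65, from 5.65 to 7.30; 12575), which encodes the cyclin-dependent kinase inhibitor p21, the antiproliferative gene Btg2 (from 4.40, below the level minimum, to 5.95), and Mdm2 (1.27, from 5.29 to 6.56), the ubiquitin ligase that acts on p53. Bbc3, which encodes the apoptosis protein PUMA, lay below the level minimum (difference 0.67). The median of 22 immediate-early and early activation genes was 0.38 (percentile 99.99; 0.75 at a level minimum of the 75th percentile), with 6 members at least 2-fold higher, among them Zfp36 (1.96), which destabilises inflammatory mRNAs, Myc (1.61) and Junb (1.28). Btg2 belongs to this list too.

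**Figure D2:**
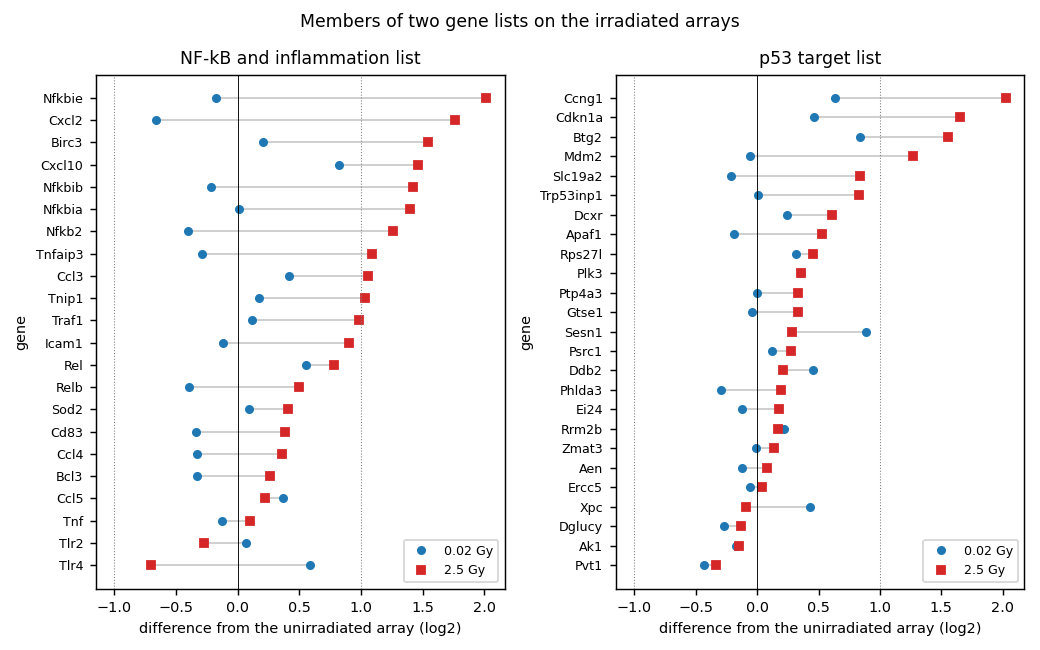
Difference from the unirradiated array (log2, horizontal axis) for each member past the level minimum of the NF-κB and inflammation list and of the p53 target list (vertical axis), with circles for 0.02 Gy, squares for 2.5 Gy and dotted lines at 2-fold. Nfkbie lies at −0.17 and 2.01 and Ccng1 at 0.63 and 2.02; each point is 1 array minus 1 array.

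Other lists lay outside the random range in high dose minus unirradiated. Splicing factor genes had a median of 0.34 (percentile 99.6; 27 of 31 above 0), and antioxidant genes 0.30 (99.9; Nfe2l2, the regulator of that response, 1.21). Both stayed outside the random range after quantile normalization and loess, at smaller medians of 0.17 and 0.18 (splicing) and 0.19 and 0.19 (antioxidant). Glycolysis and hypoxia genes had a median of 0.35 (99.9), and the call ended at a level minimum of the 75th percentile (percentile 96.3) and with list means (94.95). Core histone genes had a median of 0.36 (99.5), with 5 of 15 at least 2-fold higher, among them H4c9 (1.63), H2ac20 (1.58) and H2bc7 (1.16). H2ac20 and H2bc7 were also higher at the low dose (1.65 and 2.49), so they stood apart on the unirradiated array. The low-dose median of the list was 0.058 (31.2), inside the random range. At the high dose the median was 0.036 (63.4) with no level minimum, 0.21 (77.0) at the 75th percentile and 0.20 (98.1) after quantile normalization. Genes of the G2 and M phases were lower, with a median of −0.13 (percentile 1.39) and 16 of 24 below 0, but the call ended with no level minimum (14.1) and with list means (3.4). Double-strand break repair genes had a median of 0.04 (percentile 70.4) and pro-apoptotic genes −0.00 (41.7).

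In total, 133 genes were at least 2-fold higher and 67 lower at 2.5 Gy than in the unirradiated array, of 11593 genes. Outside the families the counts were 96 and 34. The level minimum applies to the mean of the 3 arrays, and 102 of the higher and 38 of the lower genes were at or above it on both arrays. Among genes outside the families past it on both, the mitochondrial import gene Dnajc19 was 2.23 higher, Ndufa7, a subunit gene of respiratory complex I, 1.89 higher, and Zfp936 1.35 lower. Below it on the unirradiated array were the small Cajal body RNA Scarna2 (3.72, and 6.86 at the high dose), Zfp109 (4.48 and 6.67) and the glutathione transferase gene Gstm2 (3.69 and 5.53). Below it on the high-dose array were the mitochondrial ribosome gene Mrps14 (3.88, and 5.80 unirradiated) and Socs6 (3.71 and 5.22), a suppressor of cytokine signalling.

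At 0.02 Gy, neither the NF-κB list nor the p53 target list lay outside the random range. The medians were −0.05 (percentile 8.38) and −0.00 (28.9), and no member of either list was 2-fold higher or lower. Within the p53 list, Sesn1 (0.88), Btg2 (5.24, against 4.40 unirradiated), Ccng1 (0.63) and Cdkn1a (0.46) were above 0, and Mdm2 was at −0.06. The interferon response list had a median of 0.23 (percentile 98.1; 21 of 29 above 0), with the GTPase genes Ifi47 (1.26) and Irgm1 (0.92) highest, but the call ended under 5 of 6 alternatives; after loess the median was 0.080 (85.9). The list of multipotent progenitor markers had a median of 0.35 (98.8; 6 of 9 above 0; Cd52 at 0.96), and its call also ended under 5 of 6 alternatives, with a median of 0.079 (84.1) without the level minimum. Stem cell niche adhesion genes had 22 of 23 members above 0 and a median of 0.22 (percentile 96.1), inside the random range.

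The counts at 0.02 Gy were 154 genes at least 2-fold higher and 132 lower, of which 110 and 68 were at or above the level minimum on both arrays. Families and predicted genes made up 60.6% of the lower genes, and 52 lower genes remained outside them, against 110 higher. Genes of multigene families that the rule did not cover, such as Dcpp2 and Dcpp3, are counted among the 52. The balance of higher and lower genes turned with the scaling. Higher genes were 53.8% of these in the deposited values and 64.9% after median centring, which moved the median of all genes past the level minimum from 0.04 to 0.11. They were 45.4% after quantile normalization (128 higher and 154 lower) and 45.6% after loess (124 and 148). Among genes outside the families past the minimum on both arrays, Smim14 (1.73), Nfu1 (1.72) and Hspa8 (1.67), a constitutive heat shock protein gene, were higher, and Btbd35f1 (−2.18) was lower. Below the minimum on the unirradiated array were the spermine synthase gene Sms (3.16, and 6.47 at the low dose), Scarna2 (3.72 and 6.39) and Pcdhgb2 (4.36 and 6.59). Below it on the low-dose array were Dcpp3 (4.24, and 7.40 unirradiated), Dcpp2 (3.25 and 6.14) and Pramel21 (3.36 and 5.58). Signal over background is not known here, so the size of the difference is not given for these genes. Of 212 olfactory and vomeronasal receptor genes, 0 were at least 2-fold higher and 28 lower at 0.02 Gy, against 4 and 9 at 2.5 Gy. S100a8 (1.30), S100a9 (1.12) and the histone genes H2ac20 (1.65) and H2bc7 (2.49) were higher at this dose too.

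**Figure D3:**
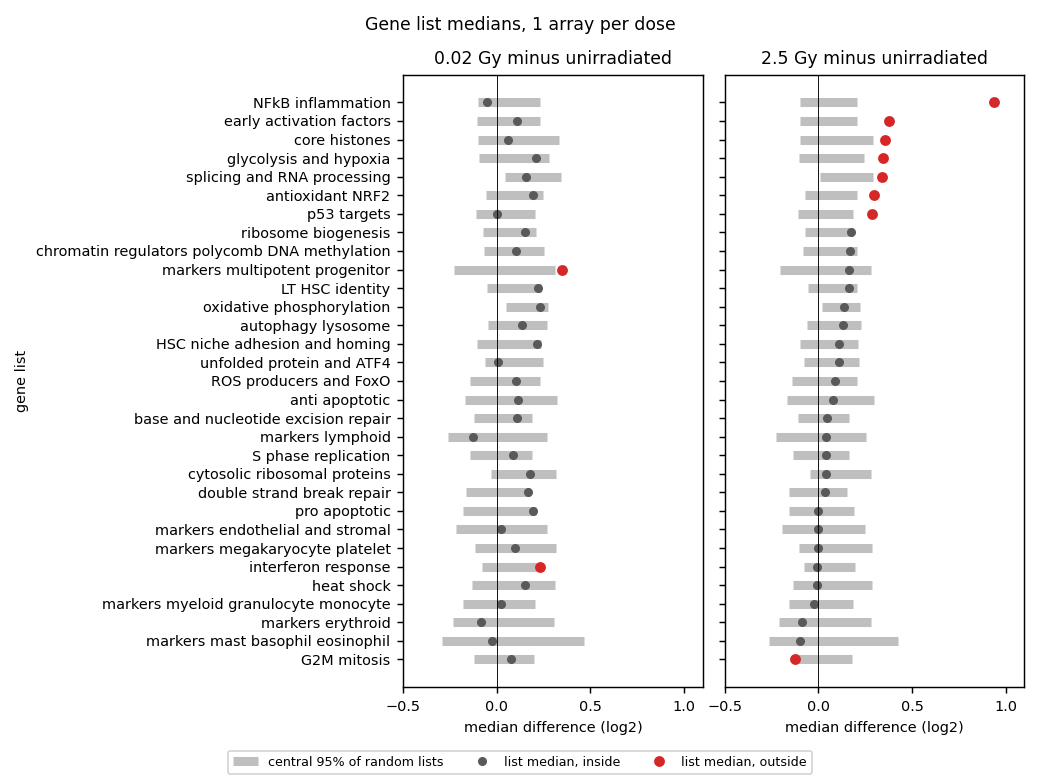
Median log2 difference from the unirradiated array (horizontal axis) for the 31 gene lists with at least 5 members past the level minimum (vertical axis), at 0.02 Gy (left) and 2.5 Gy (right); grey bars are the central 95% of 10000 random lists of like level and red points lie outside them. At 2.5 Gy 8 lists lie outside, with NF-κB at 0.94, and at 0.02 Gy 2 do. Genes drawn independently would give 1.55, and genes of a list can move together.

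The doses were also compared directly, without the unirradiated array. In high dose minus low dose, 167 genes were at least 2-fold higher and 123 lower (98 and 84 at or above the level minimum on both arrays), and 8 of 31 lists lay outside the random range. NF-κB genes had a median of 0.79, above all random lists, with 8 members at least 2-fold higher and 1 lower. Cxcl2 was 2.42 and Nfkb2 1.66 higher, while Nfkbie (4.44, and 6.63 at the high dose) and Nfkbib (4.44 and 6.08) lay just below the level minimum on the low-dose array. p53 target genes had a median of 0.20 (percentile 99.6; 0.33 at a level minimum of the 75th percentile), with Ccng1 (1.39), Mdm2 (1.33), Cdkn1a (1.19) and the thiamine transporter gene Slc19a2 (1.06) at least 2-fold higher. Early activation genes had a median of 0.39 (99.99; 0.64 at that minimum and 0.23 without one), and Zfp36 was 1.90 higher. Splicing factor genes had a median of 0.14 (98.5), inside the random range with list means (95.4). Genes of the core histone list had a median of 0.28 (99.7). Of 15 members, 2 were at least 2-fold higher (the linker histone gene H1f2 and H2bc8) and 2 lower (H2bc7 −1.34, H2bc15 −1.26). That call ended under 3 of 6 alternatives, with no level minimum (0.042, percentile 83.8), at the 75th percentile minimum (−0.042, 45.8) and with list means (0.17, 94.7).

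Lower at 2.5 Gy than at 0.02 Gy were the G2 and M phase genes (median −0.21, percentile 0.33; Tpx2 −0.74) and the interferon genes (−0.19, 0.75; Rsad2 −1.13, Xaf1 −0.88), and both calls ended at a level minimum of the 75th percentile (7.17 and 3.66). Megakaryocyte and platelet markers had a median of −0.22 (2.44; Selp −0.87), which ended under all 6 alternatives and was 0.16 at the 75th percentile minimum. Fbxo5, an inhibitor of the anaphase-promoting complex, was lower by the same comparison at −1.68, and Psenen, a subunit gene of gamma-secretase, at −1.99. Pcdhgb2 was at 6.59 at the low dose and below the level minimum at the high dose (3.03). Among progenitor markers Cd34 was at −0.78 and Sox4 at 0.88.

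The 2 dose comparisons correlated at r = 0.462 across genes, and 66.5% of genes had the same sign. Arrays simulated without any effect, sharing the unirradiated array, gave r = 0.50 (0.484 to 0.517 over 100 runs) and 66.7%. The covariance was 0.0704, against 0.0825 (0.0783 to 0.0871) in the simulation, a difference of −0.0122. At least 2-fold higher in both were 31 genes (8 in the families), against 10.1 simulated and 1.77 for independent lists. Lower in both were 23 (16 in the families), against 10.4 and 0.763. The simulation gave all genes of a level the same normal noise, although family genes spread wider (SD 0.57 against 0.37 for protein-coding genes at the low dose). The highest simulated count of genes higher in both was 18. Only 8 of the 31 observed were in the families, so their wider spread does not account for the higher count. It may account for part of the lower count, where 16 of 23 were in the families. With 1 unirradiated array the control could not be split, so that array may account for genes of either count. The counts above the simulation therefore do not show a response to both doses. Hspa8 (1.67 and 1.69) was among the genes higher in both.

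Taking each array against both others, 58 genes were at least 2-fold higher on the high-dose array and 15 lower. On the low-dose array 46 were higher and 60 lower, and on the unirradiated array 23 were higher and 31 lower. Families and predicted genes were 24 and 5 of these on the high-dose array, 24 and 38 on the low-dose array, and 16 and 8 on the unirradiated array. Of the 58, 7 were NF-κB list members (Birc3, Cxcl2, Nfkb2, Nfkbia, Nfkbib, Nfkbie and Tnfaip3), against 0.110 for independent lists; Nfkbia and Tnfaip3 are named after their values were seen. A further 3 were p53 targets (Ccng1, Cdkn1a and Mdm2), against 0.125.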

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

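Probe sets without a gene name in the annotation table entered no comparison of the report, and some of them differed between the arrays. Past the level minimum, 20 of them were at least 2-fold higher and 11 lower on the low-dose array than on the unirradiated array. On the high-dose array 17 were higher and 4 lower. Without names or replicates these values can be read only as counts.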

How the results depend on the processing

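No paired analysis was possible because each dose has 1 array and no result comes from a test. The planned mean over probe sets of a gene moved nothing, since no symbol had more than 1 probe set, and gave no values. Random lists drawn from protein-coding genes outside the families were chosen after seeing the data. The correlation of the dose comparisons stayed between 0.44 and 0.49 under 5 alternatives, leaving out median centring, which cannot move it. All 824 values of named genes under quantile normalization and loess moved by less than the robust SD of genes of like level. That SD was 0.28 to 0.34 by decile, against a level trend of at most 0.19 for these scalings to remove. The check could hardly fail and says little about single genes. Of 480 list medians, 370 moved by less than 1 SD of random-list medians and 110 by more, leaving out median centring and the other random lists. Of the 18 list calls, 8 held under all 6 alternatives that can move a percentile, including NF-κB, p53 targets and early activation genes in both comparisons with the high dose. Counts depend on fold size and level minimum by construction, since these set which genes can be counted; where list medians moved, the cause was not tested. Signal over background is not known here, so it cannot be said which of the low genes were measured above it.

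Counts below are higher then lower, for low dose minus unirradiated, high dose minus unirradiated and high dose minus low dose. Without a level minimum they were 259 and 272, 218 and 148, and 284 and 231; at the 75th percentile 94 and 56, 84 and 29, and 84 and 68; at 1.5-fold 869 and 547, 704 and 399, and 666 and 657; at 3-fold 20 and 37, 32 and 13, and 45 and 21. After quantile normalization the first pair was 128 and 154 and after loess 124 and 148, so lower genes outnumbered higher ones. With the level minimum on both arrays of the comparison, an alternative chosen after seeing the data, the counts were 110 and 68, 102 and 38, and 98 and 84. Without the families the lower counts were 52, 34 and 80 and the higher count of high dose minus low dose was 91. Genes apart from both other arrays, without a level minimum, were 65 higher on the unirradiated array, 102 higher and 95 lower on the low-dose array, and 96 and 26 on the high-dose array. At the 75th percentile they were 7, 23 and 27, and 30 and 8. At 1.5-fold they were 153 and 215 (unirradiated), 299 and 216 (low dose), and 239 and 121 (high dose), and at 3-fold 6 and 5, 6 and 11, and 18 and 3.

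Lists outside the random range in low dose minus unirradiated numbered 4 without a level minimum, 0 at the 75th percentile, 0 after quantile normalization, 0 after loess, 1 with list means and 1 against protein-coding random lists; in high dose minus low dose they numbered 5 at the 75th percentile. In high dose minus unirradiated, medians without the level minimum were 0.036 (histones), 0.27 (early activation) and 0.37 (NF-κB), and at the 75th percentile 0.21, 0.75 and 0.84. Quantile normalization gave 0.20 for histones, 0.19 for antioxidant and 0.17 for splicing genes, and loess 0.22, 0.19 and 0.18. List means were 0.47 (p53 targets), 0.48 (histones), 0.56 (early activation), 0.82 (NF-κB) and 0.22 (glycolysis and hypoxia). In high dose minus low dose, medians without the level minimum were 0.29 (p53 targets), 0.042 (histones), 0.23 (early activation), 0.55 (NF-κB) and −0.071 (megakaryocyte markers). At the 75th percentile they were 0.33 for p53 targets and 0.64 for early activation, and the sign turned for histones (−0.042) and megakaryocyte markers (0.16); list means were 0.35 (p53 targets) and 0.17 (histones). In low dose minus unirradiated, interferon genes were at 0.094 after quantile normalization and 0.080 after loess, and progenitor markers at 0.079 without the level minimum.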

Other observations

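Several genes outside the lists stood apart on the high-dose array, and they are named here after their values were seen. They included Rela, which encodes an NF-κB subunit, Ltb, which encodes lymphotoxin beta, Tnip3, whose product binds the A20 protein, and the transcriptional repressor genes Bhlhe40 and Mxd1. The unirradiated array stood apart the other way for Hspa8, S100a8, S100a9, the amino acid transporter gene Slc38a2 and the proteasome gene Psmc1 (the last 2 also named after their values were seen), which were at least 2-fold lower there than on both irradiated arrays. Oxidative phosphorylation genes had medians of 0.23 (low dose) and 0.14 (high dose), and cytosolic ribosomal protein genes 0.18 and 0.04, all inside the random range. Xist was at 8.72, 8.71 and 8.81 on the unirradiated, low-dose and high-dose arrays.

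Of the tests below, those of myeloid and granulocyte RNA, of protein-coding random lists and of the segment and microRNA classes were chosen after the results, or part of them, had been seen. The higher NF-κB list on the high-dose array was weighed first. A trend of level between arrays as the whole cause was argued against, since the median after loess was 0.87, above every random list. RNA of mature myeloid cells was argued against as the whole cause, since the myeloid marker median of high dose minus low dose was 0.053. The member SD was 0.40, and the NF-κB list was at 0.79. The sort also removed lineage-positive cells. Of 25 measured markers, 9 lay below the level minimum. Elane, among the rest, is also a progenitor gene, and both points limit this test. Against the unirradiated array the marker median was −0.02 (8 of 16 above 0), with S100a8, S100a9 and Ly6c2 at least 2-fold higher. A percentile of 100 among protein-coding random lists decides nothing about noise in the random lists, since leaving out noisier probe sets narrows their range. A response to 2.5 Gy is therefore a hypothesis that remains, but the dose and the handling of a single array are confounded and were not tested.

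S100a8 and S100a9, abundant in granulocytes, were higher on both irradiated arrays, by a mean of 1.21 (low dose) and 1.40 (high dose). RNA of mature granulocytes could not be decided on. The 6 other genes taken as granulocyte genes and past the level minimum went both ways, with medians of −0.00 (SD 0.59) and −0.12 (SD 0.42). They ran from Lyz1 at −0.73 and −0.57 to Elane at 0.94 (low dose) and Mpo at 0.70 (high dose). Elane, Mpo, Prtn3 and Ctsg of these are also progenitor genes. That leaves Lyz1 and Csf3r (−0.52 and −0.18), which are too few and not particular enough to mature granulocytes to decide. Camp, Ltf, Ngp and Ly6g lay below the minimum, which also limits this test. Scaling by level was argued against, since after loess the means were 1.03 and 1.26. RNA of mature granulocytes stays open. An unusual unirradiated array and an effect of radiation also stay open, since both comparisons rest on that 1 array.

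Sensory receptor genes, which are not known as stem cell genes, were lower on the low-dose array, with a median of −0.24, and less so on the high-dose array, at −0.09, both below every one of 2000 random lists. Scaling by level was argued against, since after loess the medians were −0.30 and −0.11, again below every random list. Lower signal of probe sets without transcript is a candidate explanation, since immunoglobulin and T cell receptor segments (−0.12) and microRNA genes (−0.20) also lay below every random list at the low dose, and at the high dose (−0.08 and −0.06). The 2-fold counts were less alike. At the low dose 11 segments were higher and 11 lower, and 7 microRNAs higher and 11 lower, against 0 and 28 receptors. The unirradiated array alone does not account for the low-dose values, since high dose minus low dose, which leaves it out, had medians of 0.16 (receptors), 0.12 (segments) and 0.13 (microRNAs), above every random list. The design gives the dose as a biological alternative, which was not tested.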
